A study of Bos taurus with 16 samples.

How the data were processed

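RNA from rumen papillae, the projections of the rumen wall, was sequenced from 16 crossbred steers aged 344 ± 48 days, 1 library per animal. Per the labels' protocols, animals were picked by their quadrant of body weight gain and dry matter intake, which gives 4 groups of 4 animals. They had free access to 1 ration (57.35% corn, 30% distillers grains, 8% alfalfa). Polyadenylated RNA was selected with oligo-dT beads and read as single reads of 50 bases. Per the submitters' processing notes, TopHat2 2.08b and the bovine genome UMD3.1 were used. The aligner settings, the annotation release and the tool that made the coverage values are not given in the sources used here.

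The deposited file lists 2351373 regions of read coverage with 16 sample columns, which were matched to the animals by the identification number in each title. No paired analysis was possible because the labels give no replicate numbers that pair animals, and replicates are numbered in accession order. The signal values are, as deposited by the authors, the mean read coverage per base of a region times 1 factor per library. This was read from the values: single-read regions hold nearly 1 value per library, and value times length sums to 591.1 to 595.9 Mb in every library. The value of 1 read over a region of 1 read length is 0.561 to 0.9973, which gives an estimated 11.9 to 21.2 M reads per library. The file lists coverage and not read counts. Reads per region could be estimated in the same way, but no count-based test or interval was used for genes. For intergenic regions a floor of 3 times the largest 1-read value (2.99) was used. In a region of about 1 read length, a level under about that of 1 read rests on few reads. In a longer region the same level stands for more reads. In the authors' deposited table, a fold column gives the ratio of the highest to the lowest sample value with 0 set to 0.01, and another its log2 value. All regions held that ratio within 1%. The p-value column, as deposited by the authors, equals the smallest of 6 unadjusted pairwise p-values between the 4 groups in 100.0% of 6167 regions with coverage over 5 (tolerance 0.002). The authors also mark 7063 regions and give a string of 16 digits per region by a rule that is not stated. None of these derived columns was used.

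Regions were annotated in the file as exon (113576 regions), intron only (981120), intergenic (1254390) or without annotation (2286), and the median region was 50 bases long. A gene's level was that of its exon-bearing region with the highest mean over the 16 libraries, and 553 regions with exons of several genes were left out. Of 12010 genes, 9445 with a value of at least 0.5 in at least 4 libraries were tested and 2565 were not. Levels were analysed as log2(value + 0.1).

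Each gene was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options) on 4 group means over all 16 libraries. The 8 contrasts were gain, intake, their interaction, high gain with low intake minus low gain with high intake, and each group minus the mean of the other 3. All tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. Errors given as SE are those of the limma model, and ± gives the SD between animals. A gene's direction is also given as the number of libraries beyond the median of the other side.

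Of 30 gene lists fixed before the data were examined, 27 had at least 5 measured members and were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated per list, and fry was run beside it. The lists for B and plasma cells (0 measured members), erythrocytes (1) and mitochondrially encoded genes (0) were not tested. KLK10, IRX3, COL1A1, CRELD2, HDAC10, IFITM3 and VIM were placed in lists because the study is known to have discussed them, so they are not independent of these samples. The lists, the contrasts and the rule for named genes were set before the data were examined. For gain and intake that rule takes 10 genes per direction past the threshold, filled up to 8 with the smallest unadjusted p where fewer pass. For high gain with low intake minus low gain with high intake and for single groups it takes 6, filled up to 3, and for the interaction 4, filled up to 2. It adds fixed genes and up to 4 members with the smallest unadjusted p of each list described. Some genes that the rule names are not reported here; they stay in the tests and lists.

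Principal components of the log2 levels of the 9445 genes were tested by permuting the libraries among groups 100000 times. Measures with 1 value per library were compared by exact permutation tests, with 12870 arrangements for 8 against 8 libraries. Tests on 11 libraries have far fewer arrangements, so their p-values are coarser. The evenness of coverage was measured in genes with at least 6 exons, using regions of a single exon with a mean coverage of at least 2. The first-exon index is the median over 876 genes of the log2 coverage of the first exon minus that of inner exons. A difference of early minus late inner exons was taken over 2180 genes, and gene density is the number of genes within 0.5 Mb on either side.

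The test was tried on simulated data with 9445 genes, of which 200 were changed, 100 by 1 and 100 by 2 on the log2 scale. With changes added to the residuals of the 16 libraries, 12% of the smaller and 65% of the larger changes were recovered for gain, 13% and 62% for intake, and 2% and 39% for high gain with low intake minus low gain with high intake. Unchanged genes could not be called there (0 in each), because residuals leave their group means equal. For the same reason these recovery rates hold no sampling error of the contrast. With noise independent between genes, recovery was 32% and 63% for gain, 26% and 57% for intake, and 5% and 35% for the last contrast, with 3, 3 and 2 unchanged genes called. With an SD of 0.3 in every gene, 100% of the changes of either size were recovered for gain and intake, with 3 and 14 unchanged genes called, and 87% of the smaller and 100% of the larger for the last contrast, with 8 unchanged genes called. With noise independent between genes, a shifted list of 20 genes drawn at random was called, and 0 unshifted lists were. This does not show how the list test behaves where genes of a list are correlated.

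Alternatives were other pseudocounts (0.01 and 1), no filter and a stricter filter, quantile normalization, limma without its trend and robust options, sample weights, 1 surrogate variable (the iteratively reweighted algorithm of the sva package, written out in R), a threshold of 0.10, 8 libraries for the contrast of 2 groups, and each library left out in turn. Chosen after seeing the data were median-of-ratios scaling, the first-exon index as a covariate, a length-weighted mean over all exon regions, regions without a first exon, and fits without the 3 libraries with an index under -2 or the 5 with an index under -1.5. Leaving out the 5 keeps 1 library in high gain with low intake. In every contrast of that fit, the mean of this group rests on 1 animal. Intergenic regions were tested apart with the same model.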

Results

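Papillae of 16 steers were profiled in 4 groups of 4 animals each: high gain with high intake, high gain with low intake, low gain with high intake, and low gain with low intake. The series title gives the question as transcript differences in the rumen with variation in feed intake and gain. Levels are mean read coverage per base, scaled by the authors to nearly the same total in every library, and each gene is represented by its best covered exon region. The estimated depth was 17.2 ± 2.55 M reads per library in high gain with high intake, 17.8 ± 2.59 in high gain with low intake, 14.6 ± 1.90 in low gain with high intake and 14.9 ± 1.06 in low gain with low intake (SD, n = 4 each). Exons held 52.4% to 68.9% of the bases, and the mitochondrial genome 8.75% to 28.0%. Estimated reads averaged 17.5 ± 2.40 M at high gain and 14.7 ± 1.44 M at low gain (n = 8 each, exact permutation p = 0.00963, Benjamini-Hochberg 0.0578 over 6 tests, those of 3 library measures by gain and by intake). The mitochondrial share averaged 18.3 ± 6.61% at high gain and 12.6 ± 4.39% at low gain (n = 8 each, exact permutation p = 0.0615, Benjamini-Hochberg 0.123), and 20.41 ± 7.05% in high gain with low intake against 13.27 ± 5.5% in low gain with high intake (n = 4 each).

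The first principal component held 73.3% of the variance, with a share of 0.217 between groups (permutation p = 0.366, 16 libraries). It separated 5 libraries with low coverage of first exons (40.7 to 203) from the other 11 (-73.2 to -20.8). Components 2 and 3 held 4.8% and 3.5%, with shares of 0.529 and 0.526 between groups (permutation p = 0.016 and 0.0282, both 0.0423 after Benjamini-Hochberg adjustment over 3 components). The largest scores on component 2 also belong to libraries low in first exons: -46.7 and -53.5 in high gain with low intake replicates 3 and 4 and 44.7 in low gain with low intake replicate 3, with the other 13 libraries between -15.7 and 14.7. On the 500 most variable genes, the share on component 2 was 0.413 (permutation p = 0.0641, Benjamini-Hochberg 0.0962) and on component 3 0.543 (permutation p = 0.0178, Benjamini-Hochberg 0.0534). Correlations between libraries of a group ran from 0.417 to 0.95, and the highest between groups was 0.959.

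First exons were thinly covered in 5 libraries: high gain with high intake replicate 4, high gain with low intake replicates 2, 3 and 4, and low gain with low intake replicate 3. Their first-exon index was -2.53, -2.43, -1.89, -1.72 and -2.45, against -1.09 to -0.296 in the other 11 libraries. These 5 libraries listed 278 to 1212 of the 9445 tested genes at 0, against 89 to 176 in the other 11. COL1A1, which encodes the main chain of type I collagen, was listed at 0, 0.10, 2.84, 4.87 and 0.44 in them, against 24.3 to 84.3 elsewhere. COL3A1, which encodes type III collagen, stood at 78.5, 141, 78.0, 58.6 and 392.49 in the same 5 libraries. High gain held 4 of the 5 libraries and low gain 1 (Fisher's exact p = 0.282), and low intake held 4 and high intake 1 (Fisher's exact p = 0.282). The mean index was -1.49 ± 0.752 at high gain and -0.69 ± 0.723 at low gain (n = 8 each, exact permutation p = 0.046, Benjamini-Hochberg 0.123). Among the other 11 libraries, 4 of high and 7 of low gain, the index at high gain was lower by a difference of -0.408 (exact permutation p = 0.00606, Benjamini-Hochberg 0.0364).

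**Figure D1:**
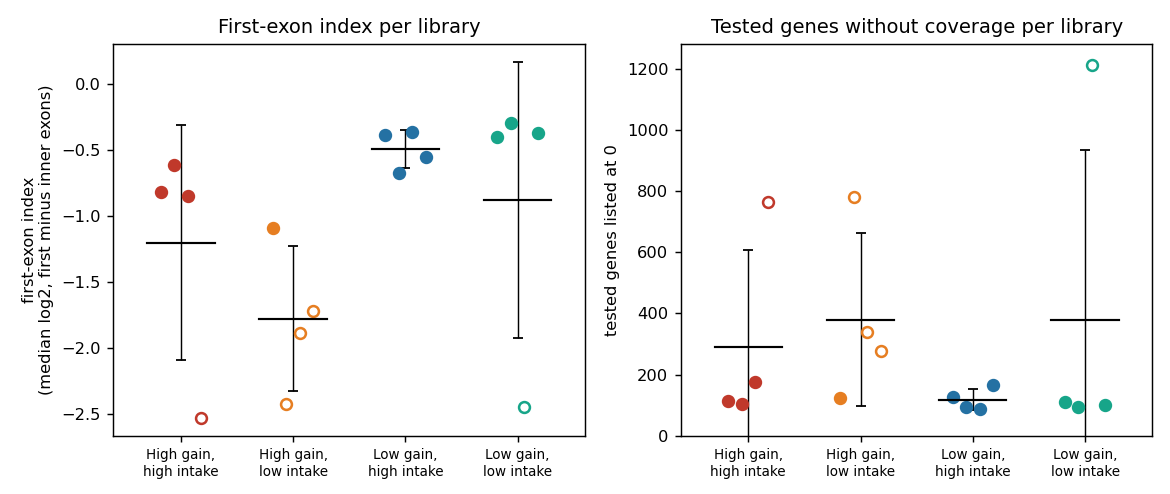
First-exon index (left, median log2 difference of first minus inner exons) and number of tested genes listed at 0 (right) per library in the 4 groups. Points are libraries (4 per group), open circles are the 5 libraries with an index under -1.5, bars are means and whiskers SD. The open circles lie between -2.53 and -1.72, the other libraries between -1.09 and -0.296.

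Gain was compared as the mean of both high-gain groups minus the mean of both low-gain groups (8 against 8 animals). Lists of stromal and vascular genes had lower estimates at high gain. Chance cannot be excluded, as 50 of 100 regroupings of the animals, the real one included, matched the smallest camera p of the 27 lists. All 10 measured smooth muscle genes had lower estimates (median log2 -1.09), among them TAGLN and CNN1, which encode actin-binding proteins of smooth muscle. TAGLN was at 6.82 ± 6.42 and 20.8 ± 11.5 at high and low gain (log2 -1.81, SE 0.66), CNN1 at 0.698 ± 0.779 and 2.35 ± 2.41, and LMOD1 at 0.215 ± 0.209 and 0.930 ± 0.615. Of 16 measured collagen and extracellular matrix genes, 15 had lower estimates (median -0.46), with ELN, which encodes elastin, at 2.30 ± 1.73 and 6.96 ± 2.93 (log2 -1.74, SE 0.47), COL6A1 at 5.02 ± 3.74 and 14 ± 6.09, and SPARC at 73.5 ± 23.3 and 103 ± 39.9. All 10 endothelial genes had lower estimates (median -0.63), with CDH5, the vascular cadherin gene, at 0.911 ± 0.362 and 1.41 ± 0.246 and CLDN5 at 0.406 ± 0.464 and 2.24 ± 1.53. All 5 measured homeobox genes had lower estimates (median -0.54), with IRX3 at 6.88 ± 1.03 and 10.6 ± 2.37 and PITX1 at 17.9 ± 15 and 49.7 ± 20.8.

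These 4 lists passed the camera test (limma, Benjamini-Hochberg adjusted p = 0.000101 for smooth muscle, 0.000101 for matrix, 0.000306 for endothelium and 0.000948 for homeobox genes). With an estimated correlation, adjusted p was 0.258, 0.178, 0.178 and 0.178. Adjusted over the list alone, the counts of lower genes were 0 for smooth muscle, 1 for matrix, 3 for endothelium and 2 for homeobox genes. Counts for matrix include COL1A1 and VIM, and those for homeobox genes IRX3, which were chosen with knowledge of the study and are not independent evidence. The proteasome list also passed (adjusted p = 0.0482, 16 of 25 members with higher estimates, median 0.14 but mean -0.02). Its adjusted p was 0.945 with an estimated correlation, and adjusted over the list alone 0 members passed. PSMA6, a core subunit, was at 12.7 ± 2.76 at high and 9.94 ± 1.49 at low gain. Leaving out the 5 libraries low in first exons keeps 1 library in high gain with low intake. That group's share of the high-gain mean then rests on 1 animal. Without the 5 libraries low in first exons, the median was -1.31 for smooth muscle (adjusted p = 0.000192), -0.29 for matrix (0.0107), -0.42 for endothelium (0.0599), -0.28 for homeobox genes (0.0599) and 0.01 for the proteasome (0.717). With an estimated correlation in these 11 libraries, adjusted p was 0.621 for smooth muscle, endothelium and homeobox genes and 0.986 for matrix and the proteasome. With the first-exon index in the model it was -0.75 for matrix (adjusted p = 1.75e-05), and no other of the 5 lists passed: smooth muscle was at -0.36 (0.364), endothelium at -0.47 (0.121), homeobox genes at -0.49 (0.0586) and the proteasome at 0.08 (0.178). With 1 library left out, the median ran from -1.73 to -0.78 for smooth muscle, from -0.55 to -0.2 for matrix, from -0.78 to -0.5 for endothelium, from -0.67 to -0.47 for homeobox genes and from 0.06 to 0.19 for the proteasome. Without low gain with low intake replicate 3, adjusted p was 0.141 for matrix, 0.0964 for homeobox genes and 0.516 for the proteasome, whose highest value over libraries left out this is.

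No single gene passed for gain (limma, 0 higher and 0 lower of 9445, smallest adjusted p = 0.636). Before adjustment 501 genes had p under 0.05 (92 higher, 409 lower), where 472 are due by chance, and limma without its trend and robust options gave 0 genes after and 517 before adjustment. The higher genes with the smallest unadjusted p, none past the threshold, included TTC22 at 15.7 ± 2.35 and 10.7 ± 1.14 (log2 0.54, SE 0.13), PABPN1, which encodes a poly(A)-binding protein of the nucleus, at 42.5 ± 8.06 and 29.9 ± 3.49 (0.49, SE 0.13), and ASIP, the agouti signalling gene, at 26.8 ± 14 and 10.5 ± 13 (3.33, SE 0.97). The innate immune genes GBP4, TLR2 and TRIM40 were at 3.08 ± 2.29 and 0.936 ± 0.928, 1.93 ± 0.667 and 0.946 ± 0.409, and 2.39 ± 0.663 and 1.02 ± 0.803. TLCD2 was at 2.87 ± 0.739 and 1.55 ± 0.411, and ENO4 at 0.610 ± 0.387 and 0.144 ± 0.156. For TTC22, 8 of 8 high-gain libraries lay above the low-gain median.

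The genes at the other end, none past the threshold either, included FBLN1, which encodes the matrix protein fibulin 1, at 14.9 ± 3.52 at high and 25 ± 6.15 at low gain (log2 -0.74, SE 0.15). PGM5 was at 2.23 ± 0.987 and 3.68 ± 0.388 (-0.80, SE 0.18), and FGFR1, a fibroblast growth factor receptor gene, at 0.292 ± 0.182 and 0.845 ± 0.263 (-1.34, SE 0.31). The other 5 had a first exon in their region, which held for 768 of the 9445 tested genes. Of these, TNFRSF12A was listed at 0 in all 8 high-gain libraries and at 0 to 5.29 at low gain. ANKRD9 was at 0 to 0.71 against 0.12 to 10.2, MTHFD2L at 0 to 0.12 against 0 to 2.20, C15H11orf31 at 0 to 2.28 against 0.27 to 104, and NDUFAB1, a gene of mitochondrial complex I, at 0 to 5.73 against 0.20 to 34.8. In regions without a first exon, NDUFAB1 and MTHFD2L differed by log2 0.19 and 0.01, opposite in sign. TTC22 was at log2 -0.02 over all its exon regions. Without low gain with low intake replicate 3, 70 genes passed, and without the 5 libraries low in first exons, 58 passed, all lower at high gain, of which 96.6% had levels correlated with the first-exon index at over 0.5 in absolute value (73.3% of all tested genes). With that index in the model 734 genes passed, 634 higher and 100 lower. These need not be the genes that passed without the 5 libraries, a fit that keeps 1 library in high gain with low intake. The correlations with the index were taken over all 16 libraries, those left out of the fit included.

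**Figure D2:**
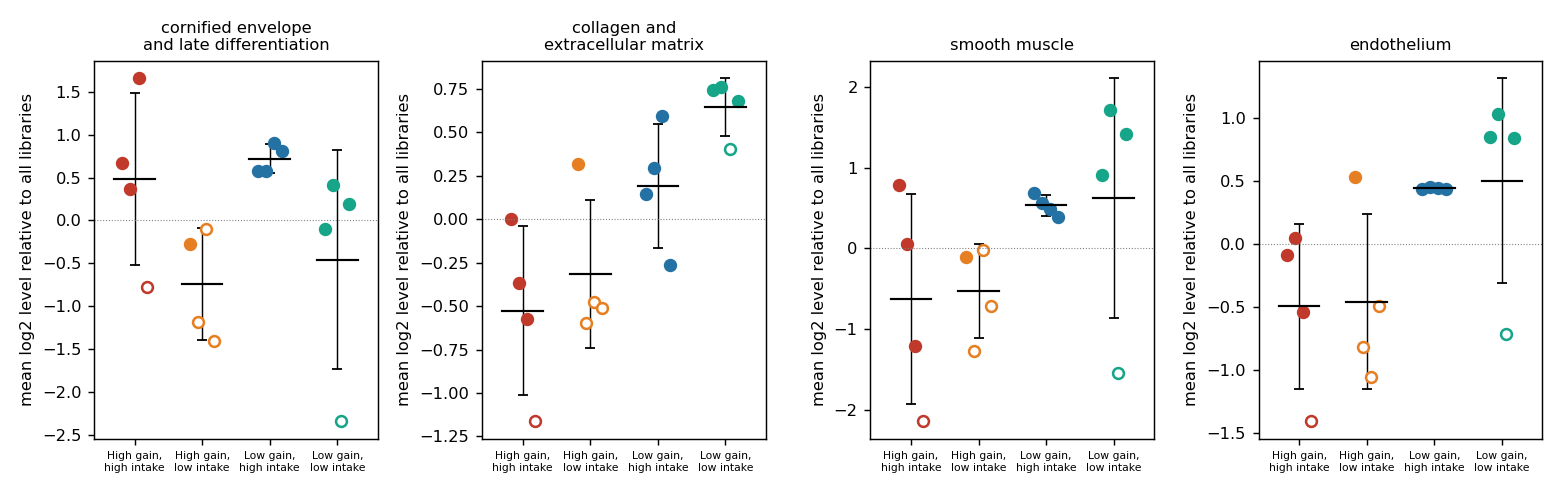
Mean log2 level of 4 gene lists per library, each relative to its mean over the 16 libraries, in the 4 groups. Points are libraries (4 per group), open circles the 5 libraries low in first exons, bars means and whiskers SD. The smooth muscle list lies lower at high gain (median log2 -1.09 over genes) and the cornified list higher at high intake (1.14).

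Intake was compared as the mean of both high-intake groups minus the mean of both low-intake groups (8 against 8 animals). In the list of genes of the cornified surface layers, 18 of 21 measured members had higher estimates at high intake (median log2 1.14). Chance cannot be excluded, as 39 of 100 regroupings of the animals, the real one included, matched the smallest camera p of the 27 lists. KLK10, an epithelial kallikrein protease gene, was at 7.91 ± 4.89 at high and 0.610 ± 0.710 at low intake (log2 3.59, SE 0.97), CNFN, the cornifelin gene, at 8.67 ± 4.50 and 2.22 ± 2.77 (2.59, SE 0.83), and S100A9, a calprotectin subunit gene, at 239 ± 168 and 80.5 ± 94.4 (2.16, SE 0.73). KLK7, another kallikrein gene of this list, was at 0.09 to 4.61 in the 8 high-intake and 0 to 0.05 in the 8 low-intake libraries (3.12, SE 0.60). The matrix list was lower, with 11 of 16 estimates negative (median -0.67). SPARC was at 66.3 ± 18.7 and 110 ± 34.4 (-0.72, SE 0.18), and FN1, the fibronectin gene, at 10 ± 3.64 and 22.1 ± 13.4. LUM was at 25.3 ± 8.12 and 56.9 ± 49.3, and COL3A1 at 64.9 ± 22.2 and 132 ± 108. The low-intake mean of COL3A1 includes 392.49 in low gain with low intake replicate 3, a library low in first exons. COL1A1 of this list had a positive estimate (1.12, SE 1.45). The unfolded protein response list was higher, with 19 of 21 estimates positive (median 0.35), 1 of them at unadjusted p under 0.05. Its chaperone genes PDIA4 and HYOU1 were at 26.4 ± 11.2 and 15.1 ± 11, and 17.6 ± 6.69 and 10.6 ± 6.52, SDF2L1 at 10.8 ± 5.88 and 5.84 ± 6.87, and SYVN1 at 5.57 ± 1.25 and 3.99 ± 2.52.

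These 3 lists passed the camera test (limma, Benjamini-Hochberg adjusted p = 1.31e-05 for the cornified list, 0.00204 for matrix and 0.00882 for the unfolded protein response). With an estimated correlation, adjusted p was 0.618, 0.618 and 0.863. Adjusted over the list alone, 2 cornified genes were higher, 2 matrix genes lower and 0 genes of the unfolded protein response passed. KLK10, COL1A1, VIM and CRELD2 are members chosen with knowledge of the study and are not independent evidence. Low intake held 4 of the 5 libraries low in first exons. Leaving these out keeps 1 library in high gain with low intake, so that group's share of the low-intake mean rests on 1 animal. Without those 5 libraries, the median was 0.40 for the cornified list (adjusted p = 9.45e-06), -0.60 for matrix (1.06e-05), and -0.10 for the unfolded protein response (0.533), where its direction turned. With an estimated correlation in these 11 libraries, adjusted p was 0.394 for the cornified list, 0.531 for matrix and 0.904 for the unfolded protein response. With the first-exon index in the model, the median was 0.48 for the cornified list (adjusted p = 1.44e-05), -0.49 for matrix (1.85e-07) and 0.27 for the unfolded protein response (0.000134). With 1 library left out, the median ran from 0.61 (without low gain with low intake replicate 3) to 1.39 for the cornified list, from -0.75 to -0.45 for matrix and from 0.15 to 0.44 for the unfolded protein response. Without high gain with high intake replicate 4, adjusted p was 0.0961 for matrix and 0.146 for the unfolded protein response, and for the latter it was 0.116 without high gain with low intake replicate 4 and 0.0668 without low gain with high intake replicate 3.

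No single gene passed for intake (limma, 0 higher and 0 lower of 9445, smallest adjusted p = 0.311), and 782 had p under 0.05 before adjustment (233 higher, 549 lower, 472 due by chance). Limma without its trend and robust options gave 0 after and 773 before adjustment. Of the 3 higher genes with the smallest unadjusted p, all are kallikrein genes between 57419897 and 57439698 on chromosome 18 (UMD3.1). KLK9 was at 0.26 to 6.30 at high and 0.03 to 0.50 at low intake (log2 3, SE 0.54, adjusted p = 0.311, limma, 8 of 8 high-intake libraries above the low-intake median). KLK8 was at 0.15 to 7.01 at high intake and listed at 0 in 7 of 8 low-intake libraries. The regions of KLK9, KLK8 and KLK7 are 1009, 276 and 802 bases long. Coverage per base there stands for more reads than over 1 read length. The lowest of their levels rest on few reads. SERPINB1, a serpin gene whose product inhibits neutrophil proteases, was at 24.1 ± 5.88 and 11.5 ± 6.20 (1.18, SE 0.27), ALOX12, a lipoxygenase gene, at 7.95 ± 3.26 and 3.43 ± 1.21, MATN4 at 1.72 ± 1.13 and 0.564 ± 0.441, C15H11orf34 at 3.36 ± 2.11 and 0.769 ± 0.648, and UNC93A at 0.605 ± 0.355 and 0.120 ± 0.141. Without high gain with high intake replicate 4, KLK9 passed (log2 3.37, adjusted p = 0.0364).

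At the other end, RBPMS was at 0.385 ± 0.241 at high and 1.54 ± 1.02 at low intake (log2 -1.65, SE 0.28, adjusted p = 0.311, limma, 8 of 8 libraries below). IGFBP7, which encodes a protein of vascular basement membranes that binds insulin-like growth factors, was at 17 ± 4.32 and 33.6 ± 13.7 (-0.94, SE 0.22), and RGS5, a pericyte marker, at 4.22 ± 1.89 and 11.7 ± 9.56 (-1.34, SE 0.33). FHL1 was at 3.95 ± 1.15 and 7.63 ± 2.09, GSTA4, a glutathione transferase gene, at 9.50 ± 4.13 and 18.9 ± 6.47 (-1, SE 0.24), and POLR1E, an RNA polymerase I subunit gene, at 3.83 ± 0.910 and 6.60 ± 1.37. SMARCA1 was at 0.248 ± 0.308 and 1.02 ± 0.384 and TRIM5 at 1.80 ± 1.34 and 5.84 ± 3.94. Adjusted p lay between 0.311 and 0.523 for the 16 genes named for intake by their unadjusted p (limma).

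**Figure D3:**
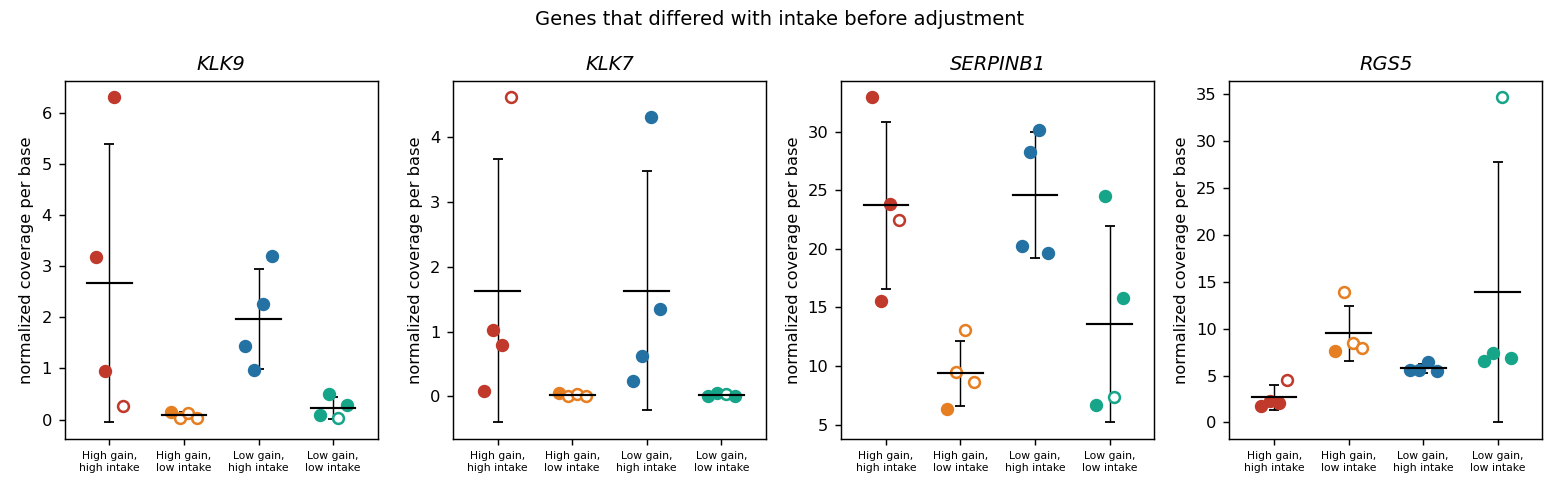
Level (normalized coverage per base) of KLK9, KLK7, SERPINB1 and RGS5 per library in the 4 groups. Points are libraries (4 per group), open circles the 5 libraries low in first exons, bars means and whiskers SD. KLK9 lies at 0.26 to 6.30 in the 8 high-intake libraries and at 0.03 to 0.50 in the 8 low-intake libraries.

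Ketogenesis, the making of ketone bodies from butyrate, and related uptake genes were described as lists fixed for this tissue. For intake, 5 of 9 ketogenesis genes had lower estimates (median -0.26, adjusted p = 0.212, camera of limma, and 0.863 with an estimated correlation), and adjusted over the list alone 1 was lower. ACAT1, which encodes a mitochondrial thiolase, was at 75.4 ± 24.3 at high and 121 ± 25.2 at low intake (log2 -0.73, SE 0.22), HADHB at 40.9 ± 10.8 and 54.5 ± 7.5, and HADHA at 21.2 ± 10.3 and 30.1 ± 15.4. The short-chain fatty acid activation list had 4 of 8 members positive (median 0.07, but mean -0.06 and a test toward lower levels, adjusted p = 0.615), with the propionate genes MCEE at 12 ± 6.01 and 19.7 ± 7.29, PCCB at 34.1 ± 12.8 and 47.5 ± 4.59 and MUT at 32 ± 16.9 and 45.1 ± 20.4, and ACACA at 2.82 ± 1.29 and 2.90 ± 2.81. In the acid and ion transport list, with 10 of 20 members positive (median 0.00, adjusted p = 0.859), SLC16A1, a carrier gene for lactate and short-chain fatty acids, was at 73.5 ± 43.6 and 144 ± 65.7 (-1.03, SE 0.33), the urea transporter gene SLC14A1 at 54.4 ± 14.1 and 81.8 ± 18.4, the sodium-proton exchanger gene SLC9A3 at 38.7 ± 17 and 20.3 ± 9.46, and SLC5A1 at 13 ± 3.17 and 9.24 ± 3.31. None of these genes passed over all genes (adjusted p = 0.528 to 0.581, limma). Of 10 endothelial genes 7 had lower estimates at high intake (median -0.31, adjusted p = 0.165), and adjusted over the list alone 3 were lower. With 1 library left out, the median ran from -0.42 to -0.1 for endothelium, from -0.36 to -0.18 for ketogenesis, from -0.2 to 0.18 for fatty acid activation and from -0.04 to 0.28 for acid and ion transport. The list members with the smallest unadjusted p were TEK at 1.45 ± 0.291 and 2.96 ± 1.4, KDR at 1.66 ± 0.863 and 3.78 ± 1.41, PECAM1 at 4.17 ± 1.03 and 6.11 ± 1.23, and CDH5 at 0.952 ± 0.310 and 1.37 ± 0.373. The fit that follows keeps 1 library in high gain with low intake. Without the 5 libraries low in first exons, the adjusted p was 0.0485 for ketogenesis (median -0.39), 0.0136 for fatty acid activation (-0.57) and 0.00393 for endothelium (-0.58). With an estimated correlation in these 11 libraries it was 0.606, 0.531 and 0.46.

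**Figure D4:**
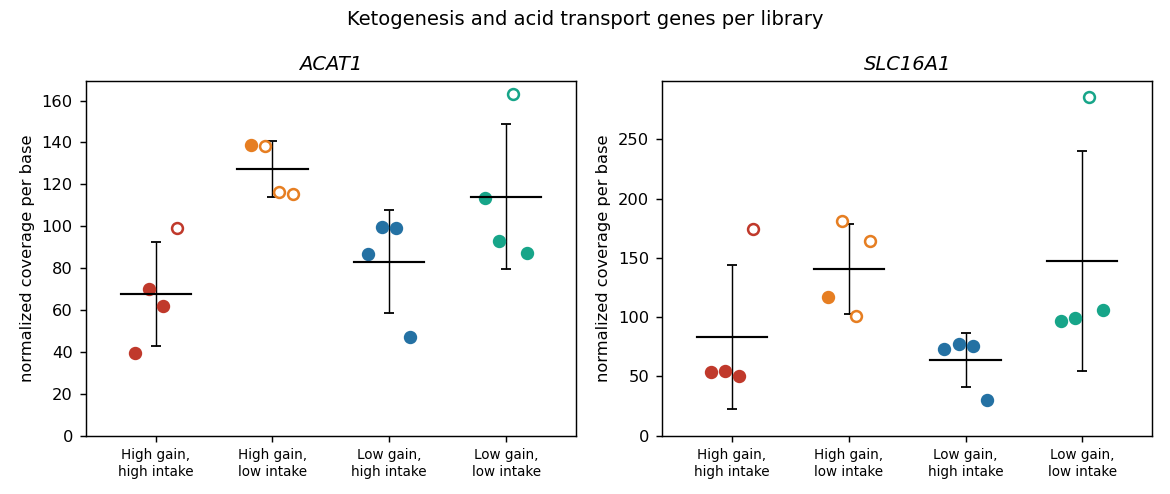
Level (normalized coverage per base) of ACAT1 and SLC16A1 per library in the 4 groups. Points are libraries (4 per group), open circles the 5 libraries low in first exons, bars means and whiskers SD. ACAT1 averages 75.4 at high and 121 at low intake, with libraries overlapping.

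The other fixed genes varied mostly within groups, in part with the libraries low in first exons. In low gain with low intake, replicate 3 was at 9.83 for KRT14 (others 319.05 to 686.36) and 53.84 for KRT5 (290.23 to 349.4). It was at 3.49 for BDH1 (131.52 to 173.65), while SLC16A1 went the other way, at 285.99 (96.41 to 106.22). KRT14 and KRT5, the basal keratin pair, were at 505 ± 328 and 165 ± 53.1 in high gain with high intake, 344 ± 284 and 138 ± 67.8 in high gain with low intake, 348 ± 128 and 210 ± 64.3 in low gain with high intake, and 371 ± 284 and 246 ± 131 in low gain with low intake (n = 4 each). In that order of groups BDH1, a ketogenic enzyme gene, was at 54.4 ± 34.8, 94.1 ± 61.3, 113 ± 45.7 and 115 ± 76.6. SLC16A1 was at 83.2 ± 60.6, 141 ± 38.1, 63.8 ± 22.6 and 147 ± 92.7. COL1A1 was at 23.7 ± 15.9, 10.5 ± 15.8, 42.5 ± 13.2 and 52.3 ± 36.1, and the interferon-induced gene IFITM3 at 5.64 ± 4.87, 2.38 ± 2.85, 11.7 ± 1.58 and 8.96 ± 6.01. IFITM3 was at 0 to 1.67 in the 5 libraries low in first exons and at 4.03 to 13.19 elsewhere. Without those 5 libraries, the log2 difference for gain moved from -2.57 to -0.69 for COL1A1 and from -1.98 to -0.80 for IFITM3. MKI67 was not analysed here.

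The interaction asked whether the gain difference at high intake differed from that at low intake. MX1, an interferon-induced antiviral gene, was at 5.15 ± 1.08 in low gain with high intake, against 1.82 ± 0.835 in high gain with high intake, 2.14 ± 1.07 in high gain with low intake and 1.04 ± 0.112 in low gain with low intake (n = 4 each, log2 -2.41, SE 0.52). FAM48A had an interaction of -1.31 (SE 0.37) and PFN4 of 3.48 (SE 1.02). None passed (limma, 0 of 9445 genes, smallest adjusted p = 1), and 49 genes had p under 0.05 before adjustment (14 higher, 35 lower, 472 due by chance). Limma without its trend and robust options gave 0 after and 52 before adjustment. No gene list passed (smallest camera adjusted p = 0.179). In the interferon response list 13 of 17 members had negative estimates (median -0.14, adjusted p = 0.179), and adjusted over the list alone 1 was lower.

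High gain with low intake, the efficient quadrant, was compared with low gain with high intake, the inefficient one (4 against 4 animals). The cornified list was lower in the efficient group, with 19 of 21 members negative (median log2 -0.83). CNFN was at 0.510 ± 0.374 in the efficient and 9.74 ± 3.91 in the inefficient group (log2 -4.13, SE 1.17), KLK10 at 0.408 ± 0.410 and 10.7 ± 3.72 (-4.80, SE 1.37), KRT36, a keratin gene, at 1.80 ± 2.47 and 32.3 ± 21.8 (-4.87, SE 1.72), and KLK7 at 0.0225 ± 0.0263 and 1.63 ± 1.84. The list passed the camera test (adjusted p = 0.0328, limma) and had an adjusted p of 0.916 with an estimated correlation. Adjusted over the list alone, 3 members were lower; KLK10 in this list was chosen with knowledge of the study and is not independent evidence. The efficient group holds 3 of the 5 libraries low in first exons and the inefficient group none. Without those 5 libraries, which leaves 1 efficient animal assumed to vary like the others, the median was -0.44 and adjusted p 0.123. With the first-exon index in the model, the median was -0.05 and adjusted p 0.471. With 1 library left out, the median ran from -1.09 to -0.6. Adjusted p was 0.121, 0.177, 0.0932 and 0.0876 without high gain with low intake replicate 1 or 4, low gain with high intake replicate 4 or low gain with low intake replicate 3.

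No single gene passed between these groups (limma, 0 of 9445, smallest adjusted p = 0.368), with 1275 at p under 0.05 before adjustment (390 higher, 885 lower, 472 due by chance) and 1274 without limma's trend and robust options, again 0 after adjustment. ASIP was at 31.5 ± 18.1 in the efficient and 4.43 ± 8.72 in the inefficient group (log2 5.69, SE 1.37), where the inefficient mean rests on replicate 3 at 17.5. GBP4 was at 3.91 ± 3.1 and 0.530 ± 0.359 and SERPINB2 at 23.4 ± 5.53 and 11.1 ± 3.98 (1.11, SE 0.28). In the other direction, KLK9 was at 0.0875 ± 0.0613 and 1.96 ± 0.981, MATN4 at 0.385 ± 0.161 and 2.28 ± 1.37, and VGLL4 was listed at 0 in all 4 efficient animals and at 1.73 ± 0.852 in the inefficient group. Adjusted p was 0.368 for each of these 6 genes (limma). Without low gain with high intake replicate 3, ASIP passed (log2 7.42, adjusted p = 0.0116). A fit to the 8 libraries of these groups alone called 735 genes (142 higher, 593 lower). There coverage of first exons cannot be told apart from the groups, since the efficient group alone holds libraries low in first exons. No regroupings were run for this count.

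Each group was also set against the mean of the other 3 (4 against 12 animals), and no gene passed in any of the 4 contrasts (limma, 0 of 9445 in each). The directions given are those of estimates with the smallest unadjusted p, not past the threshold. High gain with high intake was lower in PGM5 (1.5 ± 0.294 against 3.44 ± 0.654), PLAT, the tissue plasminogen activator gene (1.47 ± 0.395 against 3.97 ± 1.14), and RBPMS (0.277 ± 0.118 against 1.19 ± 0.979), and higher in PABPN1 (45.6 ± 8.65 against 33.1 ± 6.58), PLA2G4D (4.15 ± 2.15 against 1.72 ± 1.02) and TLR2 (2.30 ± 0.653 against 1.15 ± 0.517). The smallest adjusted p there was 0.617, and 261 genes had p under 0.05 before adjustment (269 without the trend and robust options). High gain with low intake was higher in TRIM5 (8.86 ± 3.06 against 2.14 ± 1.45), LRTOMT (1.54 ± 0.510 against 0.648 ± 0.244) and MRPL22, a mitochondrial ribosome gene (23.4 ± 4.90 against 13.3 ± 5.24), and lower in ALS2CL (0.372 ± 0.745 against 2.82 ± 1.48), SPATA2L (0.0700 ± 0.0707 against 0.642 ± 0.388) and VGLL4, listed at 0. ALS2CL was listed at 0 in replicates 2, 3 and 4 of that group, all low in first exons, and at 1.49 in replicate 1. It was at 0.31 in low gain with low intake replicate 3, against 3.88 to 4.34 in the others of its group, and its log2 moved from -3.55 to -1.06 without the 5 libraries. The smallest adjusted p was 0.594, and 782 genes had p under 0.05 before adjustment (782 without the options). Low gain with high intake was higher in MX1 (5.15 ± 1.08 against 1.67 ± 0.858), SLC9A3 (51.9 ± 9.24 against 22 ± 9.76) and MATN4 (2.28 ± 1.37 against 0.762 ± 0.535), and lower in ASIP (4.43 ± 8.72 against 23.4 ± 14.5) and CTH, a cysteine synthesis gene (1.31 ± 1.08 against 3.37 ± 1.2). The smallest adjusted p was 0.549, with 467 genes before adjustment (468 without the options). Low gain with low intake was higher in RBPMS (2.33 ± 0.872 against 0.511 ± 0.288, log2 2.07, SE 0.33), FBLN1 (28.7 ± 7.01 against 17.1 ± 4.26) and DKK3 (7.14 ± 1.36 against 3.54 ± 1.14), and lower in NT5M (0.148 ± 0.295 against 1.36 ± 0.946), C15H11orf34 (0.292 ± 0.245 against 2.66 ± 2.00) and MX1 (1.04 ± 0.112 against 3.04 ± 1.81). Its smallest adjusted p was 0.162, for RBPMS, with 232 genes before adjustment (255 without the options). Without low gain with low intake replicate 3, 72 genes passed for high gain with low intake. Without low gain with high intake replicate 3, 1 gene, ASIP, passed for low gain with high intake (log2 -6.92, adjusted p = 0.00377).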

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

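The tests of explanations in this part were all chosen after the results were seen; the rule for a library far from its group was set before the data were examined.

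A library was marked as far from its group where the gap to the nearest of the other 3, divided by the group's range, was above Dixon's 95% critical value for 4 samples. This held for 34 of 228 groups of 4 libraries, and 16 of the 34 fall in the 5 libraries low in first exons. For independent and normally distributed values about 11.4 would be due. Coverage does not meet this: a group at 0 in every library but 1 is always marked. Many of the genes were also named for their small p, so no conclusion is drawn from the excess. In high gain with high intake, replicate 4 had a first-exon index of -2.531 (others -0.846 to -0.612), 766 tested genes at 0 (103 to 176), COL1A1 at 0 (29.3 to 33.43), SLC16A1 at 174.17 (50.17 to 54.81) and GSTA4 at 19.41. In low gain with low intake, replicate 3 had an index of -2.45 (others -0.403 to -0.296), 1212 genes at 0 (93 to 111), 59.25% of bases in exons (67.52 to 68.46), IFITM3 at 0 (11.34 to 12.87), SLC16A1 at 285.99 (96.41 to 106.22), IGFBP7 at 63.92, RGS5 at 34.62 (6.5 to 7.44) and ALS2CL at 0.31. In high gain with low intake, replicate 2 had RGS5 at 13.84, and replicate 3 had FHL1 at 8.09 and KLK8 at 0.12. Replicate 1, the library of that group with more even coverage, had COL1A1 at 34.03 (0.1 to 4.87), ANKRD9 at 0.13, MTHFD2L at 0.08, ALS2CL at 1.49 and SLC9A3 at 26.05.

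The others lay in libraries with more even coverage. In low gain with high intake, replicate 3 had ASIP at 17.51 (others 0 to 0.22), KLK8 at 7.01 (0.15 to 0.67), RGS5 at 6.46 and PFN4 at 0.38, replicate 2 had ENO4 at 0.23 and SPATA2L at 0.36, and replicate 4 had SLC16A1 at 30.06. In high gain with high intake, PABPN1 was at 58.53 in replicate 1 and KLK8 at 2.09 in replicate 3. In low gain with low intake, DKK3 was at 9.16 in replicate 2, NT5M at 0.59 in replicate 1, and MATN4 at 1.61 and ENO4 at 0 in replicate 4. Outside the genes, 2655 of 45200 tested intergenic regions lay above the value of 3 reads (2.99) in all 16 libraries.

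The low first-exon index of 5 libraries was weighed. Sequencing depth is argued against, since the 5 libraries reach 21.2 M estimated reads and the other 11 run from 11.9 to 20.9. A gradual loss of 5' ends is argued against too, as the difference of early minus late inner exons reaches 0.057 in the 5, against -0.367 to -0.048 in the others. A loss of coverage in gene-dense sequence may be behind the pattern. Without first-exon regions the rank correlation of level with gene density is at most -0.134 in the 5 libraries, against 0.141 to 0.48 in the others. Levels there are relative to the mean of the 16 libraries. Leaving these regions out could change little, since 768 of the 9445 tested genes had a first exon in their region. GC content could not be measured without the genome sequence, and the labels name no batches. No biological explanation was tested: 3 of the 5 libraries are of high gain with low intake, 1 of high gain with high intake, 1 of low gain with low intake and 0 of low gain with high intake.

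The higher cornified list at high intake was weighed next. Loss of coverage stays open: without the 5 libraries the median difference fell from 1.14 to 0.40, with an adjusted p of 9.45e-06 at the preset and 0.394 at an estimated correlation. More epithelium in the sample stays open. Cornified genes rose relative to basal keratinocyte genes by 1.07 in the 11 libraries (exact permutation p = 0.0182, two-sided) and by 0.86 in all 16 (exact permutation p = 0.023). These p-values cannot decide it, since the cornified list was picked for its small p for intake in these libraries. The difference bears only on a rise of both lists alike. Chance cannot be excluded: 6 of 100 regroupings gave as small a p for this list (-log10 p 6.32, up to 9.43 in others), and 39 of 100 gave as small a p for the best of the 27 lists (6.32, up to 13.58). A difference of the epithelium with intake stays open as an untested possibility.

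The lower smooth muscle, matrix and endothelial lists at high gain were weighed last. Loss of coverage cannot be told apart from gain, as the index itself differs by gain and the lists answered unlike each other. With the index in the model the median moved from -1.09 to -0.36 for smooth muscle, from -0.63 to -0.47 for endothelium and from -0.46 to -0.75 for matrix, which alone passed (adjusted p = 1.75e-05); without the 5 libraries it was -1.31, -0.42 and -0.29, with no call at an estimated correlation (adjusted p = 0.621, 0.621 and 0.986). Less stroma in the sample stays open too: smooth muscle minus matrix genes differed by -0.42 in the 11 libraries (exact permutation p = 0.203, two-sided) and by -0.32 in all 16 (exact permutation p = 0.446). Chance cannot be excluded: the smooth muscle list was picked for its small p, which 4 of 100 regroupings matched (-log10 p 5.13, up to 7.54 in others), while 50 of 100 matched the smallest p of the 27 lists (5.14, up to 20.54). A difference in the tissue with gain is open too, as untested.

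For the counts, 100 regroupings of the animals, the real one included, show how often chance gives as much. As many genes at unadjusted p under 0.05 came in 19 for gain (real 501, highest other 3759), 9 for intake (782, 2956), 97 for the interaction (49, 5017) and 10 for high gain with low intake minus low gain with high intake (1275, 2899). For the single groups it was 27 for high gain with high intake (261, 4267), 13 for high gain with low intake (782, 3373), 25 for low gain with high intake (467, 4481) and 38 for low gain with low intake (232, 4758). As many lists past the threshold came in 28 for gain (real 5, highest other 12), 63 for intake (3, 10), 100 for the interaction (0, 12) and 86 for high gain with low intake minus low gain with high intake (1, 11). Chance cannot be excluded for any of the counts above 0. The interaction had 0 lists, which every regrouping reaches, so that count was not tested by them. Regroupings with several times the real count point to a structure of the samples other than the groups.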

How the results depend on the processing

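The fits with the first-exon index, without 3 or 5 libraries, with median-of-ratios scaling, over all exon regions and without first exons were chosen after seeing the data; the other alternatives were set before the data were examined.

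Across settings other than leaving out 1 library, single genes kept their direction and side of the threshold in 1635 of 1847 values, newly passed in 178 and turned direction in 34. Lists kept both in 74 of 116, no longer passed in 29, newly passed in 7 and turned in 6. Counts stayed within 1.5 times in 109 of 157 and moved in 48. With 1 library left out the figures were 1975 of 2000 for genes (18 newly passed, 7 turned), 186 of 208 for lists (18 no longer passed, 2 newly passed, 2 turned) and 172 of 192 for counts. The adjusted p of the cornified list for intake ranged from 3.77e-06 to 0.618 over the alternatives, the latter with an estimated correlation. At a threshold of 0.10, 0 genes passed in any contrast (limma; 49 to 1275 genes at unadjusted p under 0.05). Alternatives on estimated read counts were not run. The cause was not tested for any change given here unless a sentence says otherwise.

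With sample weights, 1740 genes passed for gain (201 higher, 1539 lower), 1178 for intake (681, 497), 1400 for the interaction (1121, 279) and 2611 for high gain with low intake minus low gain with high intake (710, 1901), with 1, 3244, 4 and 869 for high gain with high intake, high gain with low intake, low gain with high intake and low gain with low intake. As many came in 21 of 100 regroupings for gain (highest other 6077), 23 for intake (5339), 24 for the interaction (5632) and 14 for high gain with low intake minus low gain with high intake (6489), so chance cannot be excluded, and such counts point to a structure of the samples. The weights were 0.055, 0.108 and 0.253 for the 3 libraries lowest in first exons. For intake, BDH1 turned to -0.66.

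Without the 3 libraries with an index under -2, 890 genes passed for gain (25 higher, 865 lower), 17 for intake, 10 for the interaction, 1707 for high gain with low intake minus low gain with high intake, 1 for high gain with high intake and 2365 for high gain with low intake. Lists past the threshold were 5 for intake and 0 for high gain with low intake minus low gain with high intake. Only 1 of 100 regroupings, the real one, gave as many genes for gain (highest other 14), for high gain with low intake minus low gain with high intake (9) and for high gain with low intake (5). The 3 libraries were chosen after seeing the data, by the index, and regrouping the other 13 does not cover that choice, so chance stays open. Of the genes passed for gain, 98.7% had levels correlated with the index at over 0.5 in absolute value, against 73.3% of all tested genes. These correlations were taken over all 16 libraries, those left out of the fit included. Of the 3 libraries left in high gain with low intake, 2 are low in first exons. For intake, BDH1 turned to -0.71, KRT5 to -0.19 and the fatty acid activation list to -0.29.

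Without all 5 libraries, 58 genes passed for gain, all lower, 2 for high gain with low intake minus low gain with high intake, 1 for high gain with high intake and 16 for high gain with low intake, where 1 library is left and is assumed to vary like the others. For gain, 1 of 100 regroupings, the real one, gave as many (highest other 33), and 96.6% of the 58 were so correlated. Lists past the threshold were 3 for gain, 5 for intake and 0 for high gain with low intake minus low gain with high intake. For intake the values turned to -0.67 for ACACA, -0.87 for BDH1, -0.43 for COL1A1, -0.52 for KRT5, -0.12 for SYVN1, -0.57 for fatty acid activation and -0.10 for the unfolded protein response.

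With the first-exon index as a covariate, 734 genes passed for gain (634 higher, 100 lower), 2 for high gain with high intake, 64 for high gain with low intake and 30 for low gain with low intake. Lists past the threshold were 4 for gain, 9 for intake, 1 for the interaction and 3 for high gain with low intake minus low gain with high intake. Of those for gain, only matrix had passed in the main fit. For gain the values turned to 1.09 for BDH1, 0.70 for COL1A1, 0.13 for COL6A2, 0.81 for IFITM3, 0.21 for KRT5, 0.05 for NKX2-3 and -0.43 for SLC16A1. For intake they turned to -0.28 for ACACA, -0.84 for BDH1, -0.84 for COL1A1, -0.28 for IFITM3, -0.30 for KRT14, -0.26 for KRT5 and -0.25 for fatty acid activation.

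With a surrogate variable, 15 genes passed for gain, 1 for intake (RGS5), 3 for high gain with high intake and 2 for low gain with low intake. Lists past the threshold were 7 for intake, 1 for the interaction and 4 for high gain with low intake minus low gain with high intake. For gain the values turned to 0.41 for BDH1 and -0.16 for SLC16A1. For intake they turned to -0.25 for ACACA, -0.83 for BDH1, -0.73 for COL1A1, -0.22 for IFITM3, -0.27 for KRT14, -0.25 for KRT5 and -0.25 for fatty acid activation.

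With the mean over all exon regions, 2 genes passed for intake (KLK9 and KLK10) and 5 lists for the interaction. KRT14 turned to -0.37 and TTC22 to -0.02 for gain, and BDH1 to -0.28 and fatty acid activation to -0.31 for intake. With regions without a first exon, MTHFD2L turned to 0.01 and NDUFAB1 to 0.19 for gain, and 0 lists passed for high gain with low intake minus low gain with high intake (median of the cornified list -0.79). A pseudocount of 1 let 1 gene, RBPMS, pass for low gain with low intake. With only the 8 samples of the 2 groups, 735 genes passed for high gain with low intake minus low gain with high intake (142 higher, 593 lower). Of these groups only high gain with low intake holds libraries low in first exons, and no regroupings were run for this count. With an estimated correlation, 0 lists passed for gain, 0 for intake and 0 for high gain with low intake minus low gain with high intake, and with fry 2, 0 and 0. On the 500 most variable genes, the share of component 2 between groups was 0.413 (permutation p = 0.0641).

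With 1 library left out, the genes past the threshold ranged from 0 to 70 for gain and from 0 to 72 for high gain with low intake (both highest without low gain with low intake replicate 3). They ranged from 0 to 1 for intake (without high gain with high intake replicate 4), for high gain with low intake minus low gain with high intake and for low gain with high intake (both without low gain with high intake replicate 3), and stayed at 0 in the other 3 contrasts (limma). Lists ranged from 2 (without low gain with low intake replicate 3) to 6 (without low gain with high intake replicate 1) for gain, from 1 (without high gain with high intake replicate 4) to 8 (without low gain with low intake replicate 3) for intake, from 0 to 2 for the interaction and from 0 to 2 for high gain with low intake minus low gain with high intake. Values that turned ranged from -0.34 to 0.72 for KRT14 and from -0.05 to 0.35 for SLC16A1 for gain. For intake they ranged from -0.58 to 0.35 for BDH1, from -0.15 to 0.31 for KRT5 and from -0.20 to 0.18 for fatty acid activation. Depth limits the genes at low coverage in short regions: 1 read over a region of 1 read length is worth 0.561 to 0.9973, close to the minimum of 0.5.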

Other observations

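The tests on intergenic regions and the counts without 3 or 5 libraries were chosen after the results were seen.

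The lists not described with the comparisons did not pass for intake. Tight junction and adhesion genes had a median log2 of 0.54 (adjusted p = 0.104, camera of limma), T and NK cell genes 0.53 (0.111), macrophage and dendritic cell genes 0.51 (0.165), immediate early genes 0.15 (0.223), cytosolic ribosomal proteins 0.34 (0.314), glycolysis 0.21 (0.443), cholesterol synthesis 0.10 (0.615), MHC class II presentation 0.18 (0.615) and insulin and IGF signalling 0.18 (0.615). Chromatin enzymes were at 0.45 (0.727), homeobox genes at 0.08 (0.727), inflammatory cytokines at 0.16 (0.808), basal keratinocyte genes at 0.17 (0.859) and the interferon response at 0.07 (0.923). Medians below 0 were found for cell cycle genes at -0.27 (0.167), NRF2 and xenobiotic metabolism at -0.18 (0.408), heat shock proteins at -0.15 (0.859) and the proteasome at -0.12 (0.408), where the mean was 0.04. Smooth muscle genes had a median of 0.04 but a mean of -0.10 (0.615), and nuclear oxidative phosphorylation a median of 0.09 with a test toward lower levels (0.802). Adjusted over the list alone, 2 smooth muscle genes were lower, MYLK (log2 -1.26, SE 0.35) and SYNPO2 (-0.92, SE 0.28), chosen after their values were seen; 1 interferon gene, MX1, chosen likewise, was higher (0.98, SE 0.26) and 1 insulin and IGF gene, IGFBP7, lower (-0.94, SE 0.22). None of the 4 passed over all genes (adjusted p = 0.523 to 0.528).

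For gain, insulin and IGF signalling came closest to the threshold with a median of -0.41 (adjusted p = 0.0609, camera of limma, 9 of 11 members negative). Adjusted p was 0.509 for heat shock proteins (median -0.11), inflammatory cytokines (0.03), immediate early genes (-0.18), cell cycle genes (0.09), basal keratinocyte genes (-0.45) and cholesterol synthesis (0.08), and 0.536 for T and NK cell genes (-0.11) and macrophage and dendritic cell genes (-0.30). It was 0.636 for MHC class II presentation (-0.76), and 0.766 for the unfolded protein response (0.08) and cytosolic ribosomal proteins (-0.24). It was 0.886 for glycolysis (-0.01), the interferon response (-0.03), ketogenesis (-0.06), nuclear oxidative phosphorylation (-0.13), acid and ion transport (0.01), fatty acid activation (-0.05), tight junction genes (-0.42), cornified genes (-0.10), chromatin enzymes (-0.36) and NRF2 and xenobiotic metabolism (-0.06). Adjusted over the list alone, 1 inflammatory gene, TLR2, was higher. The interaction gave adjusted p of 0.179 to 0.972 over the 27 lists, and high gain with low intake minus low gain with high intake 0.227 to 0.955 over the 26 lists other than the cornified one.

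Without the 3 libraries lowest in first exons, 17 genes passed for intake (limma, 13 libraries). Of these, 94.1% had levels correlated with the first-exon index at over 0.5 in absolute value, taken over all 16 libraries. Without the 5 libraries 0 passed (922 at unadjusted p under 0.05), and with the index as a covariate 0 passed (728). Among them, chosen after their values were seen, were RGS5 at log2 -1.10 (adjusted p = 0.00372), GSTA4 at -1.01 (0.015), KLK9 at 3.13 (0.0195), MCEE at -0.81 (0.0294) and KLK10 at 4.06 (0.0474).

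Intergenic regions were tested with the same limma model, 45200 in all. No region passed for gain, intake, the interaction, high gain with low intake minus low gain with high intake or high gain with low intake. In that order, 4617, 3060, 1061, 7178 and 5446 regions had unadjusted p under 0.05, where a share of 0.05 of the 45200 is due by chance. No regroupings were run for these counts. For high gain with high intake 1 region was higher, for low gain with high intake 3 were higher (smallest adjusted p = 0.0067), and for low gain with low intake 1 was higher and 1 lower. The calls toward higher levels in these groups were all lost without the 5 libraries low in first exons. That fit leaves 1 library in high gain with low intake. Without the 5 libraries low in first exons, 99 were lower for gain, 26 for high gain with low intake minus low gain with high intake and 33 for high gain with low intake. The highest mean coverage over 16 libraries was 8860 ± 3100 in 130 bases at 17703918 of chromosome 3, 6780 ± 3880 in 692 bases at 79580774 of chromosome 14, and 6590 ± 1580 in 132 bases at 17722022 of chromosome 3 (UMD3.1, SD).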
